A study of Mus musculus with 6 samples.

How the data were processed

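Each of the 6 arrays was deposited as a scanner table with 1 line per spot, which the CodeLink Expression Analysis software, version 4.1.0.29054 per the file headers, had written. RNA had been extracted with a Ribopure kit and amplified and labelled with biotin by a MessageAmp II protocol, per the labels. The deposited raw intensity of a spot is on a linear scale and holds values below 0, so the authors' software had already subtracted a local background from it. The deposited normalized intensity is that value divided by the array's median, as the values show. The series' value table was compared with the normalized intensity column and 0 of 121734 values differed. Quality flags per spot (above background, near background, saturated, masked, contaminated, irregular) were those of the software. No genome build or probe sequence was used.

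Of 19801 gene probes, 11505 were named from the platform annotation with symbols updated through gene identifiers, 973 through a RefSeq accession in a gene table of mouse assembly GRCm38.p6 and 635 from the gene description in the scanner table, the Grb10 cDNA clone probe among these last. A further 6688 stayed unnamed. The named probes carry 12524 symbols, 573 of them on more than 1 probe. The 488 control spots were left out of the tests. Neither Il2 nor H2-K1, the genes introduced on purpose, has a probe under its name, so they are not analysed here.

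Raw intensities were used with no further background correction, since the column is already corrected. Spots marked as masked, contaminated or irregular were set to missing. Saturated spots were kept. Intensities of gene probes were quantile normalized between arrays, raised to a floor of 16.2 units (4.01 on the log2 scale), the 95th percentile of the 300 negative control spots over all arrays, and log2 transformed. Probes were kept when above background by the software's flag on both arrays of at least 1 group, which left 13054. A fold change near the floor is understated. A probe not above background on any array of a group, or saturated on every array of it, has a bound there. Its fold is given as at least the bright group's mean over the dim group's mean of, per array, the higher of the lowest normalized signal among above-background probes and the probe's own.

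Groups were taken from the sample titles. The 3 groups were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual and 3.32 prior degrees of freedom), so that they share 1 estimate of the spread, and each comparison was adjusted by Benjamini-Hochberg at 0.05. The 19 gene lists were fixed before the data were examined, and 425 of their 476 genes have a named probe. They cover antigen presentation, interferon response, mammary epithelial markers, fibroblast and extracellular matrix, insulin and growth factor signalling, imprinted genes, cell cycle, p53 and apoptosis, cytokines and chemokines, endoplasmic reticulum stress and heat shock, hypoxia and glycolysis, cholesterol biosynthesis, tumour-associated antigens, melanocyte markers, immune cell markers, retroviral and endogenous elements, ribosomal proteins, oxidative phosphorylation, and adhesion and motility. Lists were tested with camera at a preset correlation of 0.01, with the brightest probe of each gene, over genes with a value on all arrays. Counts of members use all members with a value in both groups. Some genes stand in 2 lists, such as Psmb8 and Cxcl10.

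Named genes follow a rule fixed together with the lists. They are every Grb10 probe, then per comparison and direction up to 12 named genes with the largest log2 difference among those past the threshold whose arrays do not overlap, then at most 4 members per list and comparison past 0.05 adjusted over the list alone, by smallest p. Genes outside this rule are named as such. Some genes that the rule takes are not reported here, although counts include them.

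The model was tested on simulated arrays of 12910 probes with 200 changed. At a 2-fold change it recovered 99.5% of them for immuno_high against non_selected, 99.0% for immuno_high against immuno_low and 96.0% for immuno_low against non_selected. At 1.5-fold it recovered 52.5%, 48.5% and 56.5%. Between 3.42% and 9.48% of calls were false over all runs.

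Alternatives fixed beforehand were the scanner's normalized column, median centring, cyclic loess, no filter on dim probes, a filter over all arrays, the series' value table, each array left out in turn, the replicate number as a block, the 4 arrays compared alone, a trended robust prior, 2-fold rules, and for lists an estimated correlation, fry, and the mean of a gene's probes. Normexp with an offset of 50 on the corrected intensities and a halved or doubled floor were added after the data were seen. Intensities with no background correction are not analysed here. No slide held more than 1 array, so slide was not tested as a batch. Figures were drawn with matplotlib 3.10.9.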

Results

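Gene expression was measured on 6 one-colour CodeLink mouse arrays, each hybridised with biotin-labelled RNA that, per the labels, came from transfected mouse fibroblasts of a cell-based vaccine. Per the series' design text, the vaccine was built from LM fibroblasts, a C3H/He mouse line that had been made to secrete interleukin-2 and to carry a foreign class I molecule, and that then took up a cDNA library of SB5b cells, a C3H/He mammary carcinoma line. The labels name 3 groups of 2 arrays, a non-selected vaccine (non_selected), an immuno high vaccine (immuno_high) and an immuno low vaccine (immuno_low). Of 19801 gene probes, between 11978 and 12556 were above background on an array. Across the 13054 probes kept, log2 intensities correlated at 0.996 between the non_selected arrays, at 0.997 between the immuno_high arrays and at 0.993 between the immuno_low arrays. Correlations between an immuno_high and an immuno_low array were 0.970 to 0.974, and those between a non_selected array and an array of either selected pool were 0.822 to 0.834. The immuno_low replicate 1 array carried 114 gene probes with a contaminated or irregular spot, against 8 to 21 on the other arrays, and the 95th percentile of its negative control spots was 31.5 intensity units against 10.7 to 17.7. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical, and the number of arrays limits the precision. Where both arrays of a group lay at the floor, their spread was set to 0. The SE and p-values of such probes may therefore be too small.

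The series title names Grb10, which encodes an adaptor protein that binds the insulin receptor and other receptor tyrosine kinases. The array holds 2 Grb10 probes. The cDNA clone probe gave a background-corrected intensity of 963 ± 135 (SD, n = 2) in immuno_high, 13.0 ± 3.24 (SD, n = 2) in non_selected and 10.6 ± 1.64 (SD, n = 2) in immuno_low, and it was not well above background on any non_selected or immuno_low array. Its level in immuno_high was at least 49.4-fold higher than in non_selected (limma adjusted p = 8.7e-08) and at least 56.5-fold higher than in immuno_low (limma adjusted p = 2.6e-06). The RefSeq probe was above background on all 6 arrays, at 74.2 ± 0.937 (SD, n = 2) in immuno_high, 28.6 ± 2.88 (SD, n = 2) in non_selected and 55.7 ± 8.02 (SD, n = 2) in immuno_low. It was higher in immuno_high than in non_selected by 1.30 ± 0.14 (SE) on the log2 scale (limma adjusted p = 0.00031). Against immuno_low its difference was 0.55 ± 0.14 (SE; limma adjusted p = 0.034), and this call was lost when any array other than immuno_low replicate 2 was left out (adjusted p = 0.11 to 0.20). The RefSeq probe was also 0.75 ± 0.14 (SE) higher in immuno_low than in non_selected (limma adjusted p = 0.0038), a call that was lost without non_selected replicate 1 (adjusted p = 0.072). With a normexp offset of 50, which compresses dim signals, the RefSeq probe's 3 differences shrank to 0.62, 0.29 and 0.32, and the clone probe's difference from non_selected to 3.90.

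**Figure D1:**
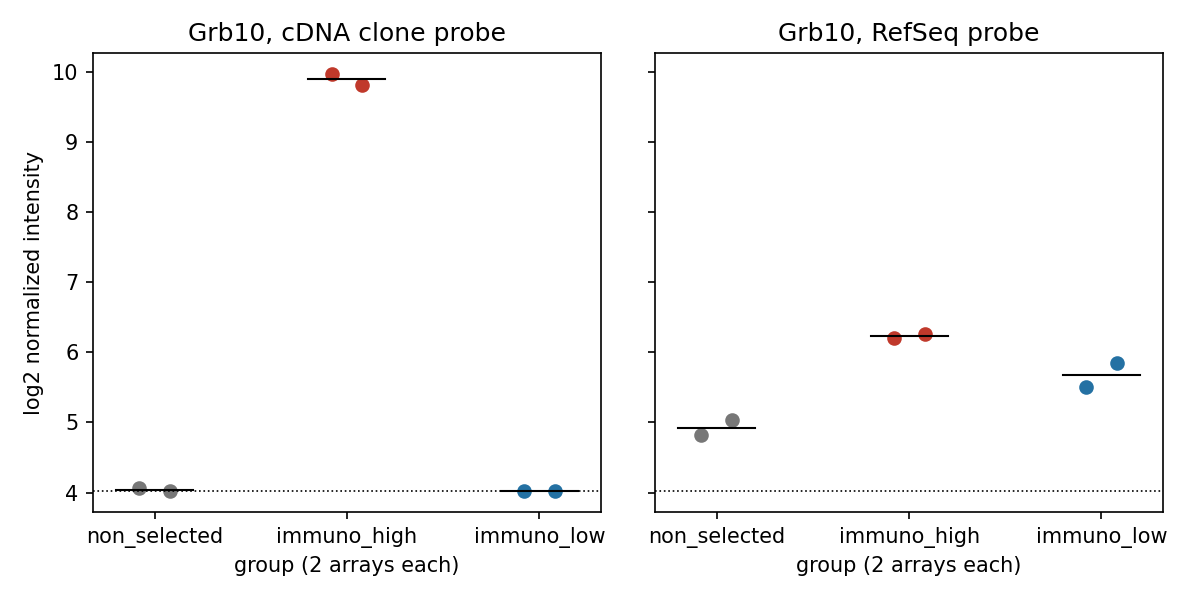
Log2 normalized intensity (vertical axis) of the cDNA clone probe (left) and the RefSeq probe (right) of Grb10 on each of the 6 arrays, by group (horizontal axis). Points are arrays, bars are group means and the dotted line is the floor of 4.01 set from the negative control spots; the clone probe averages 9.89 in immuno_high and lies at or near the floor in the other groups, and the RefSeq probe averages 6.23, 5.68 and 4.93 in immuno_high, immuno_low and non_selected.

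A cDNA enriched in the immuno high vaccine would be higher there than in both other groups. Of 13050 probes with a value in all groups, 941 were higher in immuno_high in both comparisons. By fitted values, which depend on the floor, 156 of them differed by at least 2-fold and 12 by at least 8-fold in both. The bounds can be lower, such as at least 7.13-fold for Plek, 1 of the 12, named after its values were seen. Other counts of 2-fold changes use fitted values too. Independent lists of the same sizes would share 565 probes. Simulated unchanged groups, with the same simulated immuno_high arrays in both comparisons, shared 0. A further 953 probes were called in opposite directions, and the differences correlated at 0.12 across probes against 0.50 in the simulation. The simulated groups hold noise and no effects, so these correlations cannot be compared directly. The covariance was 0.084 against 0.0092 in the simulation. Both comparisons use the same 2 immuno_high arrays, and a split that leaves 1 array to each was not run, so part of the excess may come from sharing them. Ranked by the smaller of its 2 fitted log2 differences, the Grb10 clone probe stood at rank 1, a place that depends on the floor, and the RefSeq probe at rank 557. Efemp1, an extracellular matrix glycoprotein of the fibulin family, was second, with a smaller difference of 53.1-fold, and the clone probe's bound of at least 49.4-fold lies below that, so their order is not settled. Runx1t1, a transcriptional corepressor, was at least 19.6-fold higher than in each of the other groups and Pde1a, a calcium- and calmodulin-dependent phosphodiesterase, at least 10.6-fold. Dpysl3, a cytosolic protein of neurite outgrowth, was at least 8.55-fold higher than in each of them. In all, 118 probes were above background on both immuno_high arrays and on none of the other arrays, 112 probes had that pattern for immuno_low and 591 for non_selected. The count of 941 fell to 508 with no filter on dim probes, to 326 or 385 without immuno_high replicate 2 or 1, to 533 without immuno_low replicate 1, and to 585 or 611 without non_selected replicate 1 or 2.

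Comparing immuno_high with non_selected asks which transcripts are more or less abundant in the immuno high vaccine than in the non-selected vaccine. The arrays labelled non-selected may hold RNA of another kind of cell, as taken up under the other observations. Differences from them therefore cannot be put down to selection. Camera called 3 gene lists as higher in immuno_high (fibroblast and extracellular matrix, cytokines and chemokines, antigen presentation) and the cell cycle list as lower, each with members in the other direction. None of these calls held with a correlation estimated from the residuals (adjusted p = 0.69 with an estimated correlation for each). The list calls therefore depend on the choice of setting. On simulated arrays, the 25 interferon genes were raised 1.5-fold in the first group of each comparison. With the estimated correlation their camera adjusted p was 0.011 for immuno_high against non_selected, 0.057 for immuno_high against immuno_low and 0.014 for immuno_low against non_selected. The simulated genes varied independently and no other genes were changed. The simulation thus does not show how that setting treats the real lists. Loxl1, a lysyl oxidase that cross-links elastin, reached 12.47 ± 0.03 (SD, n = 2) on the log2 scale in immuno_high and was not well above background in non_selected, a difference of at least 294-fold (limma adjusted p = 7.3e-08). Matn2, a matrix protein, was at least 160-fold higher, Pla1a, a phospholipase, at least 149.9-fold, Car13, a carbonic anhydrase, at least 136-fold, and the neutrophil chemokine Cxcl2 at least 127-fold. Fabp4, a fatty acid binding protein of adipocytes and macrophages, was 7.09 ± 0.19 (SE) higher on the log2 scale, and Rpl39l, a ribosomal protein paralog, 6.87 ± 0.12 (SE). In the other direction, Tmsb4x, which binds monomeric actin, stood at 14.36 ± 0.03 (SD, n = 2) in non_selected and was not well above background in immuno_high, a difference of at least 1232-fold (limma adjusted p = 6.3e-08). The epithelial galectin Lgals7 was at least 645-fold lower in immuno_high, the small heat shock protein Hspb1 at least 613-fold, the protease inhibitor Serpine2 at least 531-fold, the drug efflux transporter Abcg2 at least 199-fold and the tetraspanin Cd9 at least 190-fold. Over all 13052 probes tested, 4111 were higher and 3826 lower in immuno_high (limma, 60.8% of probes), 1652 and 1461 of them by at least 2-fold. These probes stand for 5978 named genes.

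Of 24 measured members of the fibroblast and extracellular matrix list, 15 were higher in immuno_high, 6 were lower and 3 did not pass (17 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.69 with an estimated correlation). Col1a2, a chain of type I collagen, was at least 81.7-fold higher and S100a4, a calcium-binding protein of fibroblasts, 5.85 ± 0.10 (SE) higher on the log2 scale. In the mammary epithelial list, 7 of 11 measured members were lower, 2 were higher and 2 did not pass (2 higher and 7 lower adjusted over the list alone). That list was not called (camera adjusted p = 0.081, with 0.025 under median centring and 0.044 without non_selected replicate 1). The epithelial adhesion molecule Epcam, at 10.39 ± 0.27 (SD, n = 2) in non_selected, was at least 73.4-fold lower in immuno_high, the keratin Krt8 at least 44.5-fold, the epithelial transcription factor Elf3 at least 7.78-fold and E-cadherin, Cdh1, at least 3.49-fold. Antigen presentation genes were higher for 11 of 14 members and lower for 1, over all probes and adjusted over the list alone (camera adjusted p = 0.0061, and adjusted p = 0.69 with an estimated correlation). Among them, H2-M3 was 4.32 ± 0.11 (SE) higher on the log2 scale and the immunoproteasome subunit Psmb9 3.02 ± 0.10 (SE), while Psmb8, another immunoproteasome subunit, was at least 12.4-fold lower. Of 21 cytokine and chemokine genes, 14 were higher and 2 lower on either adjustment (camera adjusted p = 0.0061, and adjusted p = 0.69 with an estimated correlation), with Il15 at least 20.8-fold and Ccl5 at least 13.3-fold higher. Of 27 cell cycle genes, 20 were lower and 2 higher on either adjustment (camera adjusted p = 0.0009, and adjusted p = 0.69 with an estimated correlation), with cyclin E1, Ccne1, down by a log2 difference of -2.55 ± 0.13 (SE) and Aurkb by -1.26 ± 0.08 (SE). Of 25 interferon response genes 12 were higher and 4 lower, and the list was not called (camera adjusted p = 0.67). The remaining 13 lists were not called by camera either, with adjusted p-values of 0.12 or more.

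**Figure D2:**
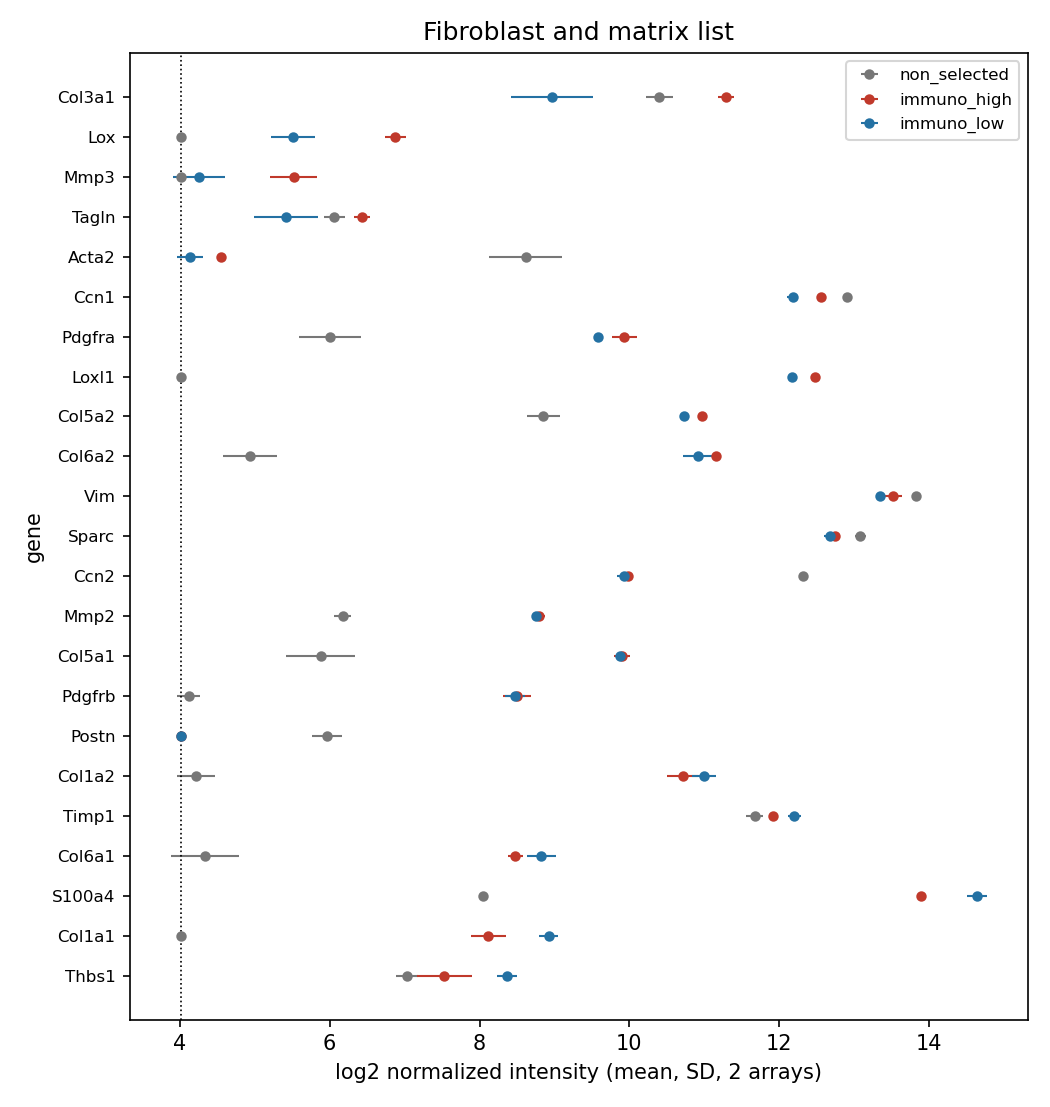
Log2 normalized intensity (horizontal axis) of 23 measured genes of the fibroblast and extracellular matrix list (vertical axis). Points are means over the arrays of a group, bars are SD over 2 arrays and the dotted line is the floor of 4.01; Loxl1 averages 12.47 in immuno_high and 12.17 in immuno_low and lies at the floor in non_selected.

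The selected pools were compared with each other next, since their labels name opposite outcomes of selection. Camera called the interferon response list as lower in immuno_high, with 22 of 26 members lower, and the cholesterol biosynthesis list as higher, with 13 of 20 members higher. Neither call held with a correlation estimated from the residuals (adjusted p = 0.36 and adjusted p = 0.42 with an estimated correlation). In this comparison that setting also missed the simulated list raised 1.5-fold (camera adjusted p = 0.057). Those simulated genes varied independently, whereas the estimated correlation was 0.285 for the interferon list and 0.366 for the cholesterol list. The simulated miss therefore does not decide how far these calls hold. Irf7, a transcription factor that drives type I interferon genes, stood at 7.53 ± 0.21 (SD, n = 2) in immuno_high and 12.41 ± 0.01 (SD, n = 2) in immuno_low on the log2 scale, a difference of -4.88 ± 0.23 (SE; limma adjusted p = 8.8e-05). The difference was -4.45 ± 0.16 (SE) for Ifit3, -4.23 ± 0.10 (SE) for the chemokine Ccl5, -3.99 ± 0.24 (SE) for the guanylate-binding protein Gbp3 and -3.95 ± 0.16 (SE) for the nucleic acid sensor Zbp1. Xlr3a was at least 31.2-fold and the germ cell gene Tex19.1 at least 27.9-fold lower in immuno_high. Higher in immuno_high, besides the Grb10 clone probe and Efemp1 with a log2 difference of 5.73 ± 0.12 (SE), were the acute phase gene Saa3 at least 24.6-fold, the pentraxin Ptx3 at least 16.9-fold and the prostaglandin synthase Ptgs2 at least 9.83-fold. Aldh1a1, a retinaldehyde dehydrogenase, was 3.90 ± 0.12 (SE) higher on the log2 scale, and Akr1b7, an aldo-keto reductase, 3.60 ± 0.33 (SE), a call that was lost without immuno_high replicate 1 (adjusted p = 0.054). Of 13051 probes, 1794 were higher and 1580 lower in immuno_high (limma), 311 and 292 of them by at least 2-fold. The total of 3374 fell to 1733 with no filter on dim probes, to 2191 with the scanner's normalized column, and to 996, 1049 or 1931 without immuno_high replicate 2, immuno_high replicate 1 or immuno_low replicate 1. It was 2132 or 2137 without non_selected replicate 1 or 2.

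Of 26 measured members of the interferon response list, 22 were lower in immuno_high, 1 was higher and 3 did not pass (24 lower and 1 higher adjusted over the list alone). Camera gave an adjusted p of 2.2e-13 and a median difference of -1.94 on the log2 scale, and the adjusted p = 0.36 with an estimated correlation. Ifit1 differed by -3.25 ± 0.13 (SE) and Oas1a, a sensor of double-stranded RNA, by -2.81 ± 0.15 (SE). The member that was higher in immuno_high, named after its values were seen, was the RNA sensor Ifih1, at least 2.25-fold. Cholesterol biosynthesis genes were higher for 13 of 20 members and lower for 0 (16 higher adjusted over the list alone; camera adjusted p = 7.6e-06, and adjusted p = 0.42 with an estimated correlation). Squalene synthase, Fdft1, differed by 1.57 ± 0.12 (SE) and the sterol oxidase Msmo1 by 0.96 ± 0.11 (SE). Of 27 cell cycle genes, 19 were lower and 0 higher (24 lower adjusted over the list alone; camera adjusted p = 3.1e-08, and adjusted p = 0.36 with an estimated correlation), among them Cenpa at -0.80 ± 0.09 (SE), Aurka at -0.90 ± 0.10 (SE) and Ccne2 at -0.83 ± 0.09 (SE). The endoplasmic reticulum stress list had 10 of 23 members higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.025, and adjusted p = 0.36 with an estimated correlation). There Chac1 was 1.75 ± 0.10 (SE) and the transcription factor Atf4 0.99 ± 0.10 (SE) higher. In the hypoxia and glycolysis list 8 of 22 members were higher and 1 was lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.025, and adjusted p = 0.83 with an estimated correlation), with Ero1a at 1.56 ± 0.09 (SE) and Egln3 at 1.37 ± 0.11 (SE). Of 14 antigen presentation genes, 6 were lower and 0 higher (7 lower adjusted over the list alone; camera adjusted p = 0.025, and adjusted p = 0.36 with an estimated correlation), including the peptide transporter Tap1 at -1.17 ± 0.12 (SE) and Psmb10 at -1.09 ± 0.14 (SE). These last 3 lists lost their call when certain arrays were left out, and the hypoxia and antigen presentation lists also with the floor doubled (adjusted p = 0.088 for both). The hypoxia list, which fry did not call either (adjusted p = 0.051), had an adjusted p of 0.079, 0.082, 0.14 and 0.12 without non_selected replicate 1, non_selected replicate 2, immuno_high replicate 2 and immuno_low replicate 2. The antigen presentation list had 0.079, 0.082 and 0.10 without non_selected replicate 1, non_selected replicate 2 and immuno_low replicate 1, and the endoplasmic reticulum stress list 0.059 without immuno_high replicate 1.

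**Figure D3:**
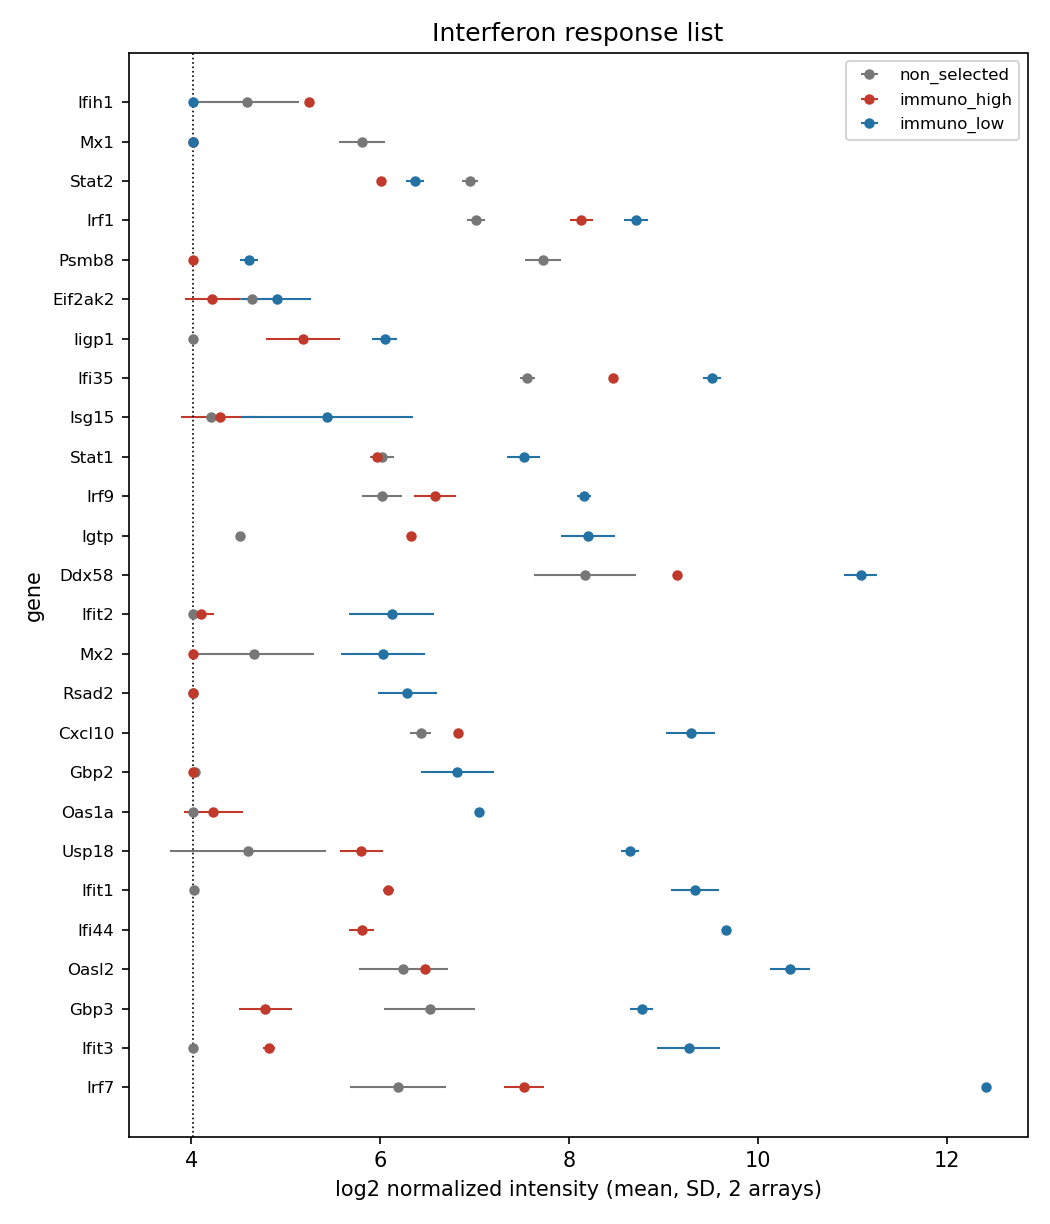
Log2 normalized intensity (horizontal axis) of the 26 measured genes of the interferon response list (vertical axis), with means over the arrays of a group as points, SD over 2 arrays as bars and the floor of 4.01 as a dotted line; Ifi44 has no usable spot in non_selected. Irf7, at the bottom, averages 12.41 in immuno_low and 7.53 in immuno_high.

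The remaining 13 lists were not called between the selected pools by camera. The fibroblast and matrix list had 6 of 24 members higher in immuno_high and 4 lower (adjusted p = 0.90). The mammary epithelial list had 1 of 11 higher and 1 lower (adjusted p = 0.79). In the retroviral and endogenous element list 7 of 14 were lower and 3 higher (adjusted p = 0.057, and 0.023 under median centring), with the RNA deaminase Adar at -2.18 ± 0.16 (SE) and Trex1 at -1.43 ± 0.10 (SE). The cytokine and chemokine list had 4 of 21 higher and 7 lower (adjusted p = 0.13, and 0.023 without immuno_low replicate 2). Of 8 measured immune cell markers, 1 was higher and 3 were lower (adjusted p = 0.70). The melanocyte list had 0 of 7 members past the test in either direction (adjusted p = 0.99) and the imprinted gene list 2 of 12, both lower (adjusted p = 0.70). Of the tumour-associated antigen list, 2 of 13 were higher and 2 lower (adjusted p = 0.90). The insulin and growth factor list had 3 of 19 higher and 0 lower (adjusted p = 0.36), among them Igfbp4 at 1.95 ± 0.12 (SE). Ribosomal protein genes were higher for 4 of 27 and lower for 0 (adjusted p = 0.14, and 0.0031 under median centring). Oxidative phosphorylation genes were higher for 3 of 24 and lower for 2 (adjusted p = 0.70), genes of the p53 and apoptosis list higher for 6 of 21 and lower for 4 (adjusted p = 0.94), and adhesion and motility genes higher for 2 of 19 and lower for 5 (adjusted p = 0.79).

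Immuno_low was compared with non_selected as the counterpart of the first comparison, with the same limit on what the non-selected arrays may hold. The chemokine Ccl5 stood at 12.23 ± 0.14 (SD, n = 2) on the log2 scale in immuno_low and was not well above background in non_selected, a difference of at least 249-fold (limma adjusted p = 7.0e-08). Loxl1 was at least 239-fold higher in immuno_low, the serpins Serpinb9g and Serpinb9e at least 198-fold and 121-fold, Col1a2 at least 99.6-fold, S100a4, saturated in immuno_low, at least 96.3-fold, and the interferon-induced GTPase Ifi47 at least 75.6-fold. Tmsb4x was at least 1251-fold lower, Hspb1 at least 622-fold, Serpine2 at least 539-fold and Abcg2 at least 202-fold, and Lgals7 differed by -8.78 ± 0.12 (SE) on the log2 scale. Over 13051 probes, 3995 were higher and 4112 lower in immuno_low (limma), 1709 and 1601 of them by at least 2-fold.

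Interferon response genes were higher in immuno_low for 20 of 25 members and lower for 3 (20 and 4 adjusted over the list alone; camera adjusted p = 0.00053, and adjusted p = 0.73 with an estimated correlation). Irf7 was 6.22 ± 0.23 (SE) higher on the log2 scale, Ifit1 at least 33.5-fold and Ifit3 at least 32.0-fold. Cytokine and chemokine genes were higher for 16 of 21 and lower for 2 on either adjustment (camera adjusted p = 0.0022, and adjusted p = 0.73 with an estimated correlation), with Il15 at least 12.9-fold higher. Antigen presentation genes were higher for 11 of 14 and lower for 1 on either adjustment (camera adjusted p = 0.0027, and adjusted p = 0.63 with an estimated correlation), with Tap1 at 3.30 ± 0.12 (SE). The fibroblast and matrix list had 15 of 24 members higher and 8 lower on either adjustment and was not called (camera adjusted p = 0.071, with 0.031 under median centring). In the mammary epithelial list 6 of 11 were lower and 3 higher (camera adjusted p = 0.19), with Epcam at least 79.8-fold and Krt8 at least 45.2-fold lower. Immune cell markers were higher for 3 of 8 and lower for 1 (adjusted p = 0.94), with the invariant chain Cd74, which is also induced by interferon, at least 59.1-fold higher. The remaining 13 lists were not called in this comparison by camera, with adjusted p-values of 0.15 or more. Over the 3 comparisons, the median, the mean and the direction of the camera test differed in sign for 12 of the uncalled and 0 of the called results.

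Differences from non_selected in the selected pools correlated at 0.92 across 13050 probes, which are not independent replicates. Simulated unchanged groups, with the same simulated non_selected arrays in both comparisons, gave a correlation of 0.50. The covariance of the measured differences was 1.67 against 0.00923 in the simulation. Of the probes, 3195 were higher in both pools and 3155 lower in both, against 1258.5 and 1205 for independent lists and 0.02 and 0.01 in the simulation. A split that leaves 1 non_selected array to each comparison was not run, so part of the excess may come from sharing them. Opposite directions were called for 123 probes.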

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

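Tests in this part were set after the results were seen, except those of the immuno_low replicate 1 array and of scaling, which were set before. For 8 named genes reported here, the difference from non_selected passed the test in opposite directions in the selected pools, and the difference between the pools, tested in the same limma model, passed as well. On the log2 scale, the fitted difference between the pools (immuno_high minus immuno_low) was 4.68 for Saa3 and 4.14 for Ptx3, values that depend on the floor, since both genes were not above background in immuno_low and are known to be at least 24.6-fold and 16.9-fold higher in immuno_high. It was 3.60 for Akr1b7, 2.32 for Col3a1, 1.56 for Ero1a, 0.99 for Atf4 and 0.63 for Atp5b. Each of these 7 genes was higher than non_selected in immuno_high and lower in immuno_low. Without immuno_high replicate 1 the calls between the pools for Akr1b7, Col3a1 and Atp5b were lost (adjusted p = 0.054, 0.059 and 0.059), and without immuno_high replicate 2 that for Atp5b (0.065), where the highest adjusted p over the alternatives was 0.054, 0.059 and 0.065. Gbp3 went the other way, at -3.99 between the pools, with -1.74 in immuno_high and 2.24 in immuno_low. Among all named genes, 96 had opposite calls of this kind, 64 of them higher in immuno_high and 32 higher in immuno_low.

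Gbp3 belongs to the interferon response list, of which 22 of 26 measured genes were lower in immuno_high than in immuno_low and 1 was higher. The array of immuno_low replicate 1, which had the most contaminated or irregular spots, was tested as a source by leaving it out, and the list's median difference was then -1.68, with a camera adjusted p of 6.0e-11 at the preset correlation (with all arrays, adjusted p = 0.36 with an estimated correlation). Scaling between arrays would move the list's median, and with median centring it was -1.89 against -1.94. Both settings align the centres of the arrays, so little movement could occur. Before scaling, the median intensities were 52.2 and 52.4 on the immuno_high arrays and 58.4 and 56.2 on the immuno_low arrays. These are too close to give a difference of that size. Of 23 immune cell probes, 0 were above background on both immuno_low arrays and on neither immuno_high array, which argues against immune cells among the immuno_low cells, although the leukocyte genes Ncf4 and Cd209c, outside that list, were higher in immuno_low, at least 16.8-fold and with a log2 difference of -4.71, and Cd68 differed by -0.54 (not past the test without immuno_high replicate 1, adjusted p = 0.057); 6 and 7 were above background on both immuno_low and both immuno_high arrays, with Cd74, the brightest, at 10.16 ± 0.08 and 9.54 ± 0.10 (SD, n = 2). A difference that came with selection and a passing interferon response of a culture, since the arrays of a pool may share 1 culture, both stay open and were not tested.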

How the results depend on the processing

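Normexp with offset 50 and a halved or doubled floor were chosen after seeing the data. Of the probes called in each comparison, 0 were called in the opposite direction under any alternative. For immuno_high against immuno_low, the 3374 probes became 2191 with the scanner's normalized column and with the series' value table, which hold the same values, and 1733 with no filter, where more probes were tested. Probes higher in immuno_high than in both other groups numbered 508 with no filter against 941. A 2-fold minimum left 3113, 603 and 3310 probes for immuno_high against non_selected, immuno_high against immuno_low and immuno_low against non_selected, and 156 higher than in both. The 2-fold rule without overlap and without a p gave 3120, 628, 3321 and 159, where chance alone separates 33.3% of probes of any fold. Leaving out 1 array, with the lone array assumed to vary like the other groups, gave 996 to 2675 probes for immuno_high against immuno_low and 326 to 682 higher than in both, with fewer arrays in the fit. It moved the difference of the Grb10 RefSeq probe between 0.39 and 0.72 against immuno_low, and between 0.57 and 0.94 for immuno_low against non_selected, where the adjusted p ranged from 0.00072 to 0.072 over the alternatives. Against immuno_low that probe was not past the threshold with no filter (0.55, adjusted p = 0.16) or with the floor doubled (0.55, adjusted p = 0.058), over a range of adjusted p from 0.016 to 0.20, and the cause was not tested. The Grb10 clone probe was past the threshold against both groups in each alternative run that kept it, with log2 differences from 3.90 to 6.10 against non_selected and from 3.98 to 6.52 against immuno_low, and it was not kept by the filter over all arrays. With the correlation estimated, camera called 0, 0 and 0 lists against 4, 6 and 3, and fry, which does not compare a list with other genes, called 15, 9 and 15. The estimated correlation of the antigen presentation list was -0.016, under the preset 0.01, so correlation between genes does not explain why that list was lost. That of the endoplasmic reticulum stress list, 0.0017, was under the preset too. The other called lists lay above it, at 0.080 for fibroblast and matrix, 0.221 for cytokines and 0.252 for cell cycle. It was 0.285 for interferon response, 0.366 for cholesterol and 0.380 for hypoxia. Their adjusted p-values at the preset may therefore be too small. Fry's direction was opposite to camera's for 3 lists that camera did not call, the retroviral and endogenous element list for immuno_high against non_selected (median -0.078) and, for immuno_low against non_selected, the endoplasmic reticulum stress list (median 0.19) and the melanocyte list (median -0.11), and the cause was not tested. Of 266 values of named genes, 223 kept their call under each alternative run, 43 lost it in at least 1 and 0 reversed. Replicate numbers recur in each group, but deviations of same-numbered arrays correlated at 0.04, -0.03 and -0.01 across probes, so the numbers were not taken as pairs. With the replicate block 7730, 3036 and 7878 probes were called, against 7937, 3374 and 8107. Intensities with no background correction were not run. Signal over background limits what can be seen, since 60.5% to 63.4% of gene probes on an array were above background.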

Other observations

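The tests in this part were set after the results were seen, except that of how often probes of a gene disagree. That of gene order on chromosome 14 was set before its outcome was seen, but after the chromosome's shift was seen. Several features outside the rule for named genes were chosen after their values were seen. A probe for the endogenous mammary tumour provirus MTV-17 stood at 14.04 ± 0.16 (SD, n = 2) on the log2 scale in non_selected and was not well above background in either selected pool, at least 986-fold lower in immuno_high and at least 1001-fold lower in immuno_low. The tumour suppressor gene Cdkn2a stood at 7.00 ± 0.01 (SD, n = 2) in non_selected and was not above background in the pools, at least 7.48-fold lower in immuno_high and 7.60-fold in immuno_low. Mtap, a methionine salvage enzyme, was lower in immuno_high by a fitted 6.95 ± 0.10 (SE) on the log2 scale and at least 128-fold lower in immuno_low. The fitted value depends on the floor, since Mtap averaged 4.12 in immuno_high and was above background on 1 of its 2 arrays. Of 12 measured genes of the imprinted list, 4 were higher and 5 lower in immuno_high than in non_selected (camera adjusted p = 0.96). Among the lower ones, Ndn and Phlda2 were at least 19.5-fold and 27.7-fold lower in immuno_high than in non_selected, with similar bounds of 19.8-fold and 30.0-fold in immuno_low. Ceacam1, a cell adhesion molecule of epithelia, was at least 24.2-fold lower in immuno_high.

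The arrays labelled non-selected stand apart from both selected pools, although the labels describe all 3 groups as transfected fibroblasts. The scanner's flags, which precede any scaling, split immuno_high from non_selected at 1451 probes, 3.88 times as many as they split immuno_high from immuno_low, which argues against scaling between arrays. Weaker signal on the non-selected arrays would remove probes one way, but 49.0% of the 1143 probes that separate these arrays from both pools were above background in the pools and the rest on the non-selected arrays. Probes with a masked, contaminated or irregular spot on the dim side were left out here, unlike in the count of 591 probes given above. A candidate explanation is that the arrays labelled non-selected hold RNA of another kind of cell, such as the mammary carcinoma line that the design text names as the library's source. Of the mammary epithelial probes that separate these arrays from both pools, 4 were above background on the non-selected arrays and 1 in the pools. Of the fibroblast probes, 1 and 6 were (two-sided Fisher's exact test, p = 0.072), which leaves this open. Changes that came with selection stay open too, since both arrays of the group may come from 1 culture. Vim and Sparc, fibroblast list members chosen after their values were seen, stood at 13.83 and 13.08 on the non-selected arrays. However, 15 of the list's 24 measured members were lower there than in immuno_high and 6 were higher, so these genes do not decide it. The MTV-17, Epcam and Krt8 probes, also picked after their values were seen, were above background on both non-selected arrays and on no array of the pools.

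The Grb10 probes disagree in the size of their difference between the selected pools, at least 56.5-fold for the clone probe, which was not above background in immuno_low, against 1.47-fold for the RefSeq probe. Ordinary disagreement between probes would be common, but among 397 genes with 2 or more measured probes Grb10 had the widest gap between fitted values. Grb10 alone makes up the 0.25% of genes with a gap that wide. With the clone probe at its bound the gap was 5.27 on the log2 scale against 2.26 for the next gene. A change of the whole chromosome region would move both Grb10 probes alike, so by itself it could not give their disagreement. It would move the neighbours too, but 17 measured genes next to Grb10, up to 20 coding genes away on each side, had a median difference of 0.22. However, 1 of them, Plek, singled out after its value was seen, was at least 8.16-fold higher in immuno_high and not above background in immuno_low. A RefSeq probe that were merely less sensitive would be near background in immuno_low, but it read 55.7 intensity units there, above background on both arrays. A transcript or introduced cDNA that carries the sequence of 1 probe and not of the other, and cross-hybridisation of the RefSeq probe, stay open, since probe sequences were not used here.

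Genes of chromosome 14, placed by the gene table, were higher in immuno_high than in immuno_low by a median of 0.35 on the log2 scale over 319 probes, 82.1% of them above 0, and lower in immuno_low than in non_selected with a median of -0.35. This median exceeded those of 10000 random sets of the same size, as did those of chromosomes 1 (0.14), 10 (0.15) and 6 (0.09), while those of chromosomes 18 (-0.21), 5 (-0.083) and 3 (-0.042) lay below the random sets, which describes these arrays, since genes are not replicates. Array by array, the 4 pairings of an immuno_high with an immuno_low array gave 0.31 to 0.37. If the pools differed in the number of copies of chromosome 14, the shift would run along its whole length. In gene order, 4 equal groups of its measured genes had medians of 0.27 to 0.37, as that hypothesis predicts. The chromosome was picked for its median, and 82.1% of its probes lay above 0. The 4 medians therefore show only that the shift was not confined to part of the chromosome. No DNA was measured here, and the shift may have other sources that act on many genes of a chromosome.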
